A study of Homo sapiens with 25 samples.

How the data were processed

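Files of 24 samples were used: 9 RNA-seq, 9 ATAC-seq and 6 H3K4me3 CUT&RUN libraries of HEC-1A cells. An IgG CUT&RUN sample was not analysed here. Groups came from the sample labels: untreated, 20 µM THC for 24 h and 20 µM THC for 72 h for RNA and ATAC, and untreated and THC for H3K4me3. The labels give no THC duration for H3K4me3, so it was set beside both RNA times. Replicate numbers are those of the labels. Numbers in the names of some deposited ATAC lists differ from them, and what those numbers mark is not given in the sources used here. Growth and treatment conditions beyond these are not given in the sources used here.

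Per the labels' protocols, RNA was extracted with columns and made into libraries with a stranded total RNA kit, ATAC libraries were made by transposition of lysed cells followed by bead selection and PCR, and CUT&RUN used bead-bound permeabilised cells and a protein A/G nuclease fusion. Per the submitters' processing notes, the genome build was GRCh38 and the tools were Salmon, Trim Galore, FastQC, Bowtie2, SAMtools, Picard, MACS3 and MACS2 2.2.7.1. The notes name no roles. The names of the H3K4me3 files carry macs2, and which caller made the ATAC lists is not given in the sources used here. Nor are read shifting in ATAC, duplicate removal, the control used for H3K4me3 peaks or the use of strand in counting.

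RNA values are TPM as the authors deposited them, the values of each library having the same total over 60179 Ensembl gene identifiers. TPM keeps no depth, so no count test was run, no interval from counts can be given and depth per library is unknown. A symbol was found for 59918 identifiers in a table of gene names. Because TPM sums to a constant, a rise of abundant genes lowers all others, which the alternatives address. Peaks were called per library. The fold enrichment (a ratio) of each peak is the authors' own, per the labels and the files' layout, and was not compared between lists. The deposited -log10 p and -log10 q columns were used to rank and filter peaks within a list, the lowest -log10 q being about 1.3 in ATAC lists and 2 in H3K4me3 lists. The score column deposited by the authors equals 10 times -log10 q rounded down and was not used.

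The statistical design, the gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. RNA was tested with limma 3.58.1 in R 4.3.3 (linear model over 3 groups of 3 libraries, eBayes with trend) on log2(TPM + 1) for 13753 genes with a mean TPM of at least 1 over the 9 libraries, 48 of them without a symbol. The threshold was a Benjamini-Hochberg adjusted p of 0.05 with no fold threshold. Of 34 fixed gene lists with 710 entries, 30 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Camera with a correlation estimated per list and fry were run beside it. The lists cover cholesterol synthesis, cholesterol uptake and regulation, fatty acid synthesis and desaturation, LXR targets, glycerolipids and lipid droplets, fatty acid oxidation, sphingolipids, the SWI/SNF complex and H3K4 methylation machinery. They also cover the integrated stress, unfolded protein and heat shock responses, autophagy and lysosome, NRF2 targets, AHR and xenobiotic genes, endocannabinoid genes, S phase, mitosis, p53 targets, apoptosis, ferroptosis, glycolysis and hypoxia. The rest cover nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, interferon, NF-κB, epithelial junctions, mesenchymal genes, replication histones, endometrial hormone response, and stromal, immune and endothelial markers. Older symbols were matched only where they are no current symbol of another gene.

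Named genes followed a fixed rule. Per comparison these were the 10 largest rises and 10 largest falls among called genes with a symbol, a mean TPM of at least 5 and non-overlapping groups. Added to these were up to 4 called members of each called list with the largest change, and always ARID1A, SREBF1, SREBF2, FASN, SCD, CNR1, CNR2 and GPR55. For regions the rule took, per assay and comparison, up to 5 gained and 5 lost ones at the marked end of a called gene, ranked by the size of the RNA change, and the 3 longest gained and lost ones, of which the text gives a part. Some genes that the rule names are not reported here. Genes with near-identical copies, and antisense or overlapping genes, are uncertain. Genes outside this rule are said to have been chosen after their values were seen. Calls shared by the times were set against 100 simulations of unchanged groups with the same untreated libraries.

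Peak lists were processed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 on chromosomes 1 to 22 and X, and figures drawn with matplotlib 3.10.9. Overlapping or adjoining peaks were merged over the libraries of an assay into regions, and any overlap counted as listed. A region was gained if listed in 3 of 3 THC and 0 of 3 untreated libraries, and lost if the reverse. The numbers of peaks and bases were compared with exact permutation tests, 2-sided, whose smallest p for 3 against 3 is 0.1. Presence in a list depends on a caller's threshold and on sequencing depth, so a region missing from a list is not shown to be closed or unmarked, and list lengths set how many regions can be gained or lost.

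The planned tests at transcription start sites needed the strand of each gene. The gene table used here (GRCh38.p14) has none, so the tests were run at the gene end that carried H3K4me3 in at least 2 libraries, a departure decided after the files were seen. Among 11510 tested genes longer than 4 kb, 9070 had the mark at exactly 1 end, 1472 at both and 968 at neither. Over 12686 tested genes of any length, a marked region lay at the lower end of 54.3%, and of 8.02% with positions shifted by 1 Mb. The share of 1 kb (ATAC) or 2 kb (H3K4me3) on each side of that end under peaks was tested with limma where at least 3 libraries had a peak there. Genes without exactly 1 marked end and shorter genes were left out of these tests. The RNA change of genes with gained or lost regions there was tested with camera and Fisher's exact test.

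Each step was tested on simulated data. For 24 h against untreated, with 13753 genes, limma found 26, 74, 92 and 98% of 50 genes each changed by 0.25, 0.5, 1 and 2 on the log2 scale, with 4 false calls. For camera, 1 list shifted by 1 at 72 h was the 1 list called of 30. This simulation is no measure of false list calls where the genes of a list vary together. In the real data the estimated correlation was 0.633 for the mitochondrially encoded mRNAs. A regrouping of the real 72 h and untreated libraries that mixed the groups called 16 lists with the preset correlation. Region and window overlaps matched a direct count over 7080 region cells and 398 windows, with 0 differing. For windows, changes of 10, 20, 40 and 60 percentage points were found in 0, 14, 64 and 94% of cases for ATAC (8839 windows, 6 false calls) and 22, 74, 98 and 98% for H3K4me3 (9045 windows, 10 false calls). Changes under 20 points in ATAC are therefore mostly out of reach.

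No pair of RNA libraries was identical, with correlations of 0.989 to 0.995 within groups and 0.928 to 0.960 between them. Alternatives were a pseudocount of 0.1, other filters on low genes, median centring, fits on 6 libraries, the replicate number as a block, no trend, a 2-fold threshold, other list tests, peaks with -log10 q of at least 5, equal lists, a cover of at least 50%, presence in 2 of 3 libraries, wider windows and leaving out each library. TPM rescaled without mitochondrial genes and the ferritin genes FTH1 and FTL was added after seeing the data. Closing tests on biotypes, distances to genes and mitochondrial RNA were also chosen then.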

Results

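HEC-1A cells, an epithelial line from a human endometrial adenocarcinoma, were left untreated or given 20 µM THC (tetrahydrocannabinol, the main psychoactive cannabinoid of cannabis). RNA-seq and ATAC-seq, which maps accessible DNA by transposon insertion, each had 3 untreated libraries, 3 after 24 h and 3 after 72 h. Labels give the untreated libraries no time, so time in culture and length of THC exposure cannot be told apart. CUT&RUN, which cuts DNA beside an antibody-bound protein, mapped H3K4me3, a histone mark of active promoters, in 3 untreated and 3 THC libraries whose labels give no duration. A single CUT&RUN sample with IgG was not analysed here, so 24 of 25 samples in 9 groups had a file. The RNA table held TPM for 60179 genes, and TPM keeps no sequencing depth, so depth is unknown. The ATAC lists held 38495 to 150884 peaks per library on chromosomes 1 to 22 and X, and the H3K4me3 lists 30098 to 35879. The labels call the libraries biological replicates, but nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Errors are SDs with n = 3 libraries per group unless stated, RNA p-values are limma's adjusted values, and RNA fold changes are on the log2(TPM + 1) scale, which understates low genes.

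The first comparison asked which genes respond to 24 h of THC, and whether lipid genes and the chromatin remodeller subunit ARID1A, both named in the series' title, were among them. SCD, the desaturase that makes monounsaturated fatty acids, fell from 206 ± 5.87 to 8.63 ± 0.338 TPM (log2 fold change -4.43, adjusted p = 1.38e-11). FASN, the fatty acid synthase, went from 105 ± 8.70 to 22.9 ± 5.95 TPM (-2.18, adjusted p = 5.78e-07). ACSL1, which activates long-chain fatty acids, dropped from 93.6 ± 3.88 to 10.7 ± 0.645 TPM (-3.02, adjusted p = 1.08e-10). ARID1A itself fell from 51.2 ± 1.86 to 18.6 ± 1.3 TPM (-1.41, adjusted p = 2.2e-08). In the other direction, the stress transcription factor DDIT3 rose from 26.8 ± 0.829 to 673 ± 34.0 TPM (4.60, adjusted p = 2.17e-12).

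All 20 cholesterol synthesis genes fell at 24 h (limma camera, adjusted p = 1.85e-06; adjusted p = 0.0581 with an estimated correlation). ACAT2 moved by -2.5 on the log2 scale, IDI1 by -2.11, TM7SF2 by -1.94 and SQLE, the squalene epoxidase, by -1.90. Of 15 cholesterol uptake and regulation genes, 2 rose and 12 fell (camera adjusted p = 0.0383; adjusted p = 0.355 with an estimated correlation), the call being lost without untreated replicate 3 (adjusted p = 0.055). They included LIPA (-1.55), STARD4 (-1.29) and SREBF1, a master regulator of lipid synthesis (147 ± 10.3 to 64.5 ± 6.15 TPM, -1.17). SREBF2, its relative that drives sterol genes, fell by 0.52. Among fatty acid synthesis and desaturation genes 4 rose and 14 fell of 21, without a list call (adjusted p = 0.104). No call was made for fatty acid oxidation (3 rose and 19 fell of 26, adjusted p = 0.0633), LXR targets (0 and 5 of 7, adjusted p = 0.285) or glycerolipid and lipid droplet genes (1 and 9 of 15, adjusted p = 0.405). Sphingolipid and ceramide genes were called as higher, with 8 up and 5 down of 19 (adjusted p = 0.048; adjusted p = 0.26 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.0552), without 24 h replicate 1 (adjusted p = 0.063) and after centring (adjusted p = 0.0546). UGCG, the glucosylceramide synthase, rose by 1.11 and DEGS1, the dihydroceramide desaturase, fell by 1.26.

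Of 26 SWI/SNF complex genes, which encode subunits of the remodeller that contains ARID1A, 3 rose and 22 fell at 24 h (adjusted p = 0.0274; adjusted p = 0.26 with an estimated correlation). Beside ARID1A these were PHF10 (-1.45), PBRM1 (-1.09) and SMARCB1 (-1.06). Genes of the H3K4 methylation machinery were not called as a list (5 rose and 13 fell of 20, adjusted p = 0.405). Of 10 replication histone genes 9 rose and 0 fell (adjusted p = 4.82e-06; 0.0356 with an estimated correlation, so this call held). H2BC21 (2.22), H1-2 (2.18) and H2AC6 (2.17) led, but histone copies are near-identical and their split is uncertain.

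The integrated stress response, a program that adjusts translation and amino acid supply, rose in 21 of 25 genes and fell in 3 (adjusted p = 1.04e-11; 0.0154 with an estimated correlation, so this call held). ATF3 rose from 1.41 ± 0.0308 to 63.4 ± 3.94 TPM (4.74), PPP1R15A, the phosphatase subunit that restores translation, from 39.5 ± 2.15 to 822 ± 11.8 (4.35), and SLC3A2, an amino acid transporter chain, from 103 ± 11.7 to 1482 ± 4.38 (3.84). The unfolded protein response list had 12 up and 7 down of 19 (adjusted p = 0.00483; adjusted p = 0.26 with an estimated correlation), with HERPUD1 (2.15), the chaperone HSPA5 (2.11) and XBP1 (1.89) up. Autophagy and lysosome genes were called as higher although 8 rose and 9 fell of 25 (adjusted p = 0.0327; adjusted p = 0.26 with an estimated correlation). MAP1LC3B, an autophagosome protein, rose by 2.5 and ATP6V0D1, a proton pump subunit, moved by -1.16. NRF2 targets had 9 up and 7 down of 19 (adjusted p = 0.0341; adjusted p = 0.26 with an estimated correlation), led by the haem oxygenase HMOX1 (10.9 ± 0.503 to 152 ± 6.25 TPM, 3.68). For p53 targets, 9 rose and 9 fell of 20 (adjusted p = 0.0338; adjusted p = 0.26 with an estimated correlation; 0.0785 after centring), with a median of -0.08 and a mean and test upward. CDKN1A, a brake on the cell cycle, was among the 10 largest rises of all genes (4.28 ± 0.203 to 219 ± 7.30 TPM, 5.38). Heat shock genes (3 rose and 8 fell of 14, adjusted p = 0.696), apoptosis regulators (8 and 8 of 18, adjusted p = 0.135) and ferroptosis genes (6 and 7 of 15, adjusted p = 0.362) were not called.

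Cell cycle genes fell at 24 h. The S phase list fell in 25 of 26 genes and rose in 0 (adjusted p = 2.05e-07; adjusted p = 0.13 with an estimated correlation), and the mitosis list fell in 25 of 27 and rose in 0 (adjusted p = 1.76e-06; adjusted p = 0.2 with an estimated correlation). The replication clamp PCNA went from 268 ± 11.5 to 45.3 ± 1.52 TPM (-2.54), and the proliferation marker MKI67 from 133 ± 5.15 to 38.7 ± 1.44 (-1.76). All 10 tested NF-κB and inflammation genes rose (adjusted p = 2.09e-07; adjusted p = 0.0553 with an estimated correlation), among them IL32 (2.82), TNFAIP3 (1.96) and NFKBIA (1.60). Interferon response genes rose in 14 and fell in 4 of 19 (adjusted p = 2.61e-06; adjusted p = 0.101 with an estimated correlation). RSAD2 reached 278 ± 5.64 TPM from 12.3 ± 0.699 (4.40) and ISG15 833 ± 249 from 129 ± 10.9 (2.64).

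All 13 mitochondrially encoded mRNAs fell (adjusted p = 6.57e-05; adjusted p = 0.275 with an estimated correlation), from -0.63 for MT-ATP6 to -4.79 for MT-ND6 on the log2 scale. Their summed level went from 71247 ± 3667 to 28006 ± 598 TPM. Nuclear genes of oxidative phosphorylation fell in 26 of 29 and rose in 1 (adjusted p = 0.00108; adjusted p = 0.117 with an estimated correlation), with ATP5MC1 at -1.07 and SDHA, which has near-identical copies, at -1.42. Glycolysis and hypoxia genes rose in 5 and fell in 20 of 27 (adjusted p = 0.0327; adjusted p = 0.26 with an estimated correlation), with PFKFB4 at -2.48 and NDRG1 at 2.84. Ribosomal protein mRNAs rose in 25 of 30 and fell in 0 (adjusted p = 1.22e-07; adjusted p = 0.101 with an estimated correlation), RPL10 by 0.91, though near-identical copies make single ribosomal protein genes uncertain. Epithelial junction genes had 11 up and 6 down of 19 (adjusted p = 0.00674; adjusted p = 0.26 with an estimated correlation), with KRT7 up by 0.97 and the protease ST14 at -0.93. The mesenchymal list had 5 up and 3 down of 9 (adjusted p = 0.0327; adjusted p = 0.155 with an estimated correlation; 0.0755 after centring), with SNAI2 up by 1.74 and COL1A1 at -1.23. AHR and xenobiotic genes (2 rose and 3 fell of 7, adjusted p = 0.692) and endocannabinoid genes (3 and 7 of 12, adjusted p = 0.669) were not called. The cannabinoid receptor gene CNR1 was listed at 0 in all 9 libraries, and CNR2 averaged 0.00863, 0.00370 and 0.0107 TPM in untreated, 24 h and 72 h libraries. GPR55, a further cannabinoid-binding receptor, averaged 0.561 ± 0.0818, 0.265 ± 0.0717 and 1.48 ± 0.0707 TPM. All 3 receptors lay below the filter and were not tested.

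Outside the lists that were run, the largest named rise was CD68, a lysosomal glycoprotein and macrophage marker, from 0.249 ± 0.0544 to 132 ± 4.68 TPM (6.74, adjusted p = 2.71e-11). It was the 1 tested gene of 14 immune markers, a list too small to run. PLAUR, the urokinase receptor, rose from 28.0 ± 0.928 to 1077 ± 59.0 TPM (5.21), with MMP1 (4.61), CCL5 (4.40) and ATG9B (4.18) behind it. The named falls also held MIR210HG (-4.05), KCNJ16 (-3.72), TM4SF4 (-2.99), ID4 (-2.98), TINAG (-2.95), BICC1 (-2.87) and H2AX (-2.85). Hormone response genes of the endometrium (3 tested of 18), stromal markers (3 of 12) and endothelial markers (0 of 10) were also too few to run.

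Among 13753 tested genes, limma called 3433 as higher and 7111 as lower at 24 h, and 726 rose and 1464 fell at least 2-fold. In 78.6% of tested genes the 3 libraries of one group lay above all 3 of the other, where chance gives 10%. The median change of all tested genes was -0.23, and centred counts are given relative to that shift. With each library centred on its median (a shift of -0.22), 4954 genes rose and 5128 fell, and the rising share of calls went from 32.6% to 49.1%. Rescaling TPM without mitochondrial and ferritin genes, an alternative chosen after seeing the data, left it at 32.5%. After centring the counts up and down were 22 and 3 for the integrated stress response, 0 and 20 for cholesterol synthesis, 1 and 25 for S phase, 2 and 24 for mitosis, and 3 and 18 for SWI/SNF. They were 3 and 17 for oxidative phosphorylation, 17 and 3 for autophagy, 11 and 5 for NRF2 targets, 12 and 4 for sphingolipids and 15 and 1 for the interferon response. Adjusted over the list alone, the heat shock list had 3 up and 9 down, and each of the other 29 lists had the counts given over all genes. Of 20 lists called, 2 were called with an estimated correlation. Median, mean, difference from other genes and test disagreed in sign for p53 targets, heat shock, AHR and ferroptosis genes.

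**Figure D1:**
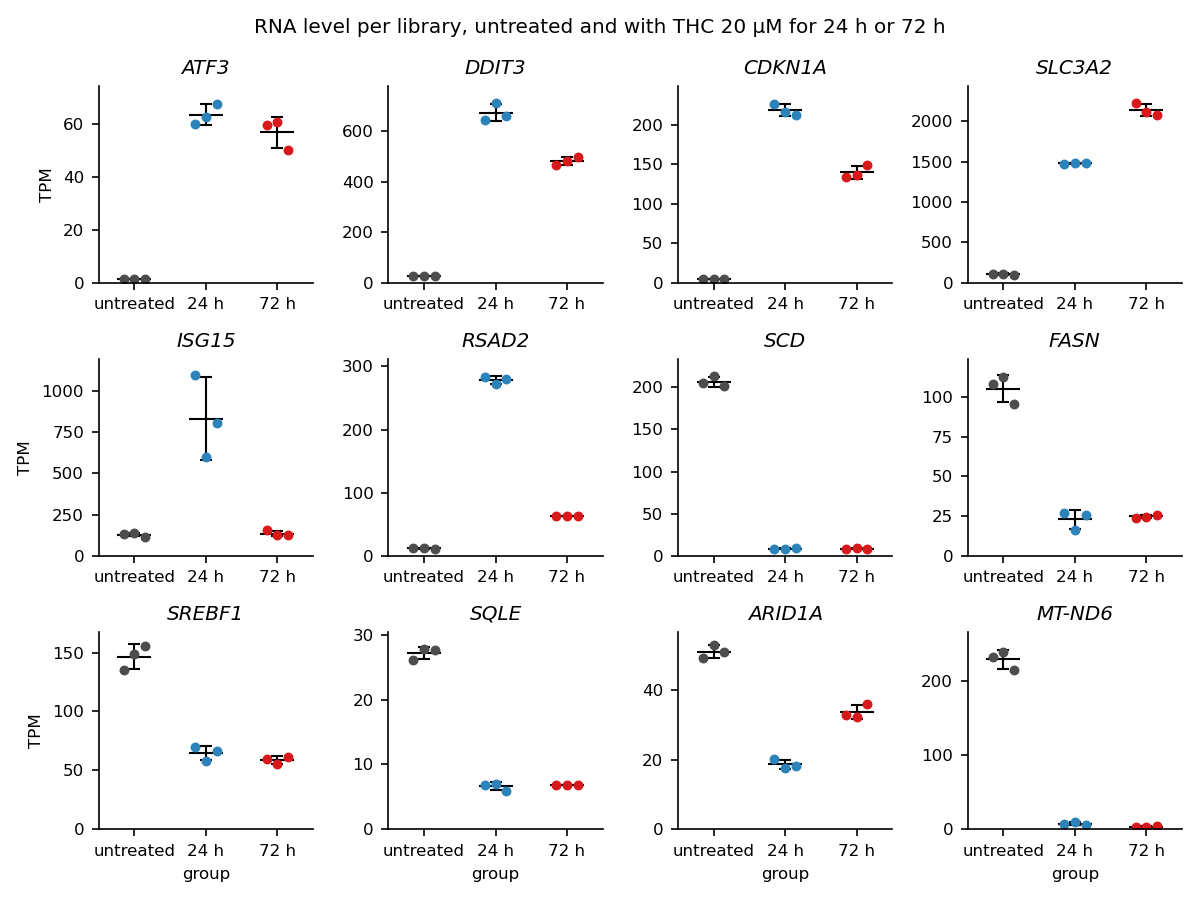
RNA level in TPM (linear axes from 0) of 12 genes in untreated libraries and after 24 h and 72 h of THC, with a dot per library, a line at the mean and bars of 1 SD (n = 3). SCD stands at 206, 8.63 and 8.59 TPM, ARID1A at 51.2, 18.6 and 33.8, and ISG15 at 129, 833 and 135.

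At 72 h the question was whether these changes lasted. SCD stayed low at 8.59 ± 0.701 TPM against 206 ± 5.87 in untreated cells (-4.44, adjusted p = 2.03e-11), and FASN at 24.8 ± 0.945 (-2.04, adjusted p = 1.07e-06). SREBF2 reached 92.4 ± 3.42 TPM from 161 ± 7.32 (-0.80, adjusted p = 2.15e-07). ARID1A stood at 33.8 ± 2.04 TPM, below untreated cells (-0.59, adjusted p = 1.4e-05). HMOX1 rose to 231 ± 6.23 TPM (4.28, adjusted p = 4.93e-12) and SLC3A2 to 2142 ± 75.2 (4.37, adjusted p = 4.29e-11).

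All 20 cholesterol synthesis genes were lower at 72 h (adjusted p = 8.76e-10; 0.0376 with an estimated correlation, so this call held), with ACAT2 at -2.34, SQLE at -1.85 and HMGCS1 at -1.64. Cholesterol uptake and regulation genes had 2 up and 10 down of 15 (adjusted p = 0.00274; adjusted p = 0.227 with an estimated correlation), among them INSIG1, which retains the SREBP complex (96.1 ± 4.78 to 19.2 ± 2.44 TPM, -2.27). Fatty acid synthesis genes had 4 up and 13 down of 21 (adjusted p = 0.00876; adjusted p = 0.225 with an estimated correlation). Fatty acid oxidation genes had 6 up and 15 down of 26 (adjusted p = 0.0346; adjusted p = 0.271 with an estimated correlation). In that list ANGPTL4, a lipase inhibitor, moved by -2.71, while ACADVL (1.21) and CPT1B (1.12) rose. SWI/SNF genes had 6 up and 14 down of 26 (adjusted p = 0.0281; adjusted p = 0.271 with an estimated correlation), with the ATPase SMARCA4 at -0.73. LXR targets (3 rose and 3 fell of 7, adjusted p = 0.784), glycerolipid genes (7 and 5 of 15, adjusted p = 0.921), sphingolipid genes (12 and 2 of 19, adjusted p = 0.0622) and the H3K4 machinery (7 and 7 of 20, adjusted p = 0.838) were not called. Sphingolipid genes were called without 72 h replicate 1 (adjusted p = 0.0403).

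The integrated stress response rose in 23 of 25 genes and fell in 0 (adjusted p = 4.79e-10; 0.0263 with an estimated correlation, so this call held), with ATF3 at 4.58, PPP1R15A at 4.13 and DDIT3 at 4.12. The unfolded protein response rose in 15 and fell in 1 of 19 (adjusted p = 9e-05; adjusted p = 0.146 with an estimated correlation), HERPUD1 to 298 ± 8.56 TPM (2.89). Autophagy genes rose in 16 and fell in 1 of 25 (adjusted p = 0.0079; adjusted p = 0.146 with an estimated correlation), with MAP1LC3B at 2.47 and WIPI1 at 2.05. Heat shock genes rose in 1 and fell in 11 of 14 (adjusted p = 0.00215; adjusted p = 0.112 with an estimated correlation), with the chaperones HSP90AA1 at -1.24 and HSPE1 at -1.39. The mitosis list fell in all 27 genes (adjusted p = 2.35e-10; adjusted p = 0.105 with an estimated correlation) and the S phase list in 23 of 26, with 0 up (adjusted p = 3.83e-09; adjusted p = 0.105 with an estimated correlation). MKI67 was at -1.67 and CDC6, a replication licensing factor, at -1.31. All 10 NF-κB genes rose (adjusted p = 0.000138; adjusted p = 0.105 with an estimated correlation), RELB by 1.86. Replication histones had 8 up and 1 down of 10 (adjusted p = 0.0165; adjusted p = 0.112 with an estimated correlation).

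The mitochondrial mRNAs fell further, all 13 being lower than in untreated cells (adjusted p = 4.79e-10; adjusted p = 0.146 with an estimated correlation), at -5.86 for MT-ND6, -3.76 for MT-CO2 and -3.13 for MT-CO1. Their summed level was 10451 ± 986 TPM. Nuclear oxidative phosphorylation genes fell in 25 of 29 and rose in 0 (adjusted p = 2.54e-07; 0.0441 with an estimated correlation, so this call held). Glycolysis and hypoxia genes rose in 4 and fell in 21 of 27 (adjusted p = 3.66e-06; adjusted p = 0.105 with an estimated correlation), with PGAM1, which has near-identical copies, at -2.11 and BNIP3 at -2.01. Ribosomal protein mRNAs rose in 26 and fell in 1 of 30 (adjusted p = 1.14e-05; adjusted p = 0.133 with an estimated correlation). No call was made for NRF2 targets (9 rose and 9 fell of 19, adjusted p = 0.878), p53 targets (9 and 3 of 20, adjusted p = 0.097), apoptosis (8 and 7 of 18, adjusted p = 0.955) or ferroptosis (8 and 6 of 15, adjusted p = 0.863). The interferon list (9 and 7 of 19, adjusted p = 0.955), epithelial (5 and 7 of 19, adjusted p = 0.864), mesenchymal (5 and 3 of 9, adjusted p = 0.557), AHR (2 and 4 of 7, adjusted p = 0.591) and endocannabinoid genes (6 and 3 of 12, adjusted p = 0.546) were not called either.

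Single genes that stood out at 72 h were CD68 (4.75), CDKN1A (4.74), ATG9B (4.46), LINC01564 (4.25) and LCN2, an iron-carrier binding protein (0.551 ± 0.208 to 35.2 ± 0.692 TPM, 4.55). TREM1, a receptor known from myeloid cells, went from 0.0161 ± 0.028 to 17.8 ± 1.48 TPM (4.21). The falls included TM4SF4 (-4.92), TINAG (-4.24), SFTA1P (-3.81), ANKRD2 (-3.56), AMBP (-3.52), TESC (-3.48) and CST6 (-3.40). In all, 5514 genes rose and 4542 fell, 1123 and 764 of them at least 2-fold, and 76.6% of genes had non-overlapping groups, against 10% by chance. Centring (a shift of 0.09) gave 4790 up and 5347 down, with 24 up and 2 down for ribosomal proteins and 14 up and 5 down for autophagy. Adjusted over the list alone, S phase had 25 down, the unfolded protein response 16 up and the H3K4 machinery 7 up and 8 down, and each of the other 27 lists had the counts given over all genes. Of 17 lists called, 3 were called with an estimated correlation. Median, mean, difference from other genes and test disagreed in sign for 5 lists, none of them called: LXR targets, glycerolipid, H3K4 machinery, NRF2 and apoptosis genes.

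**Figure D2:**
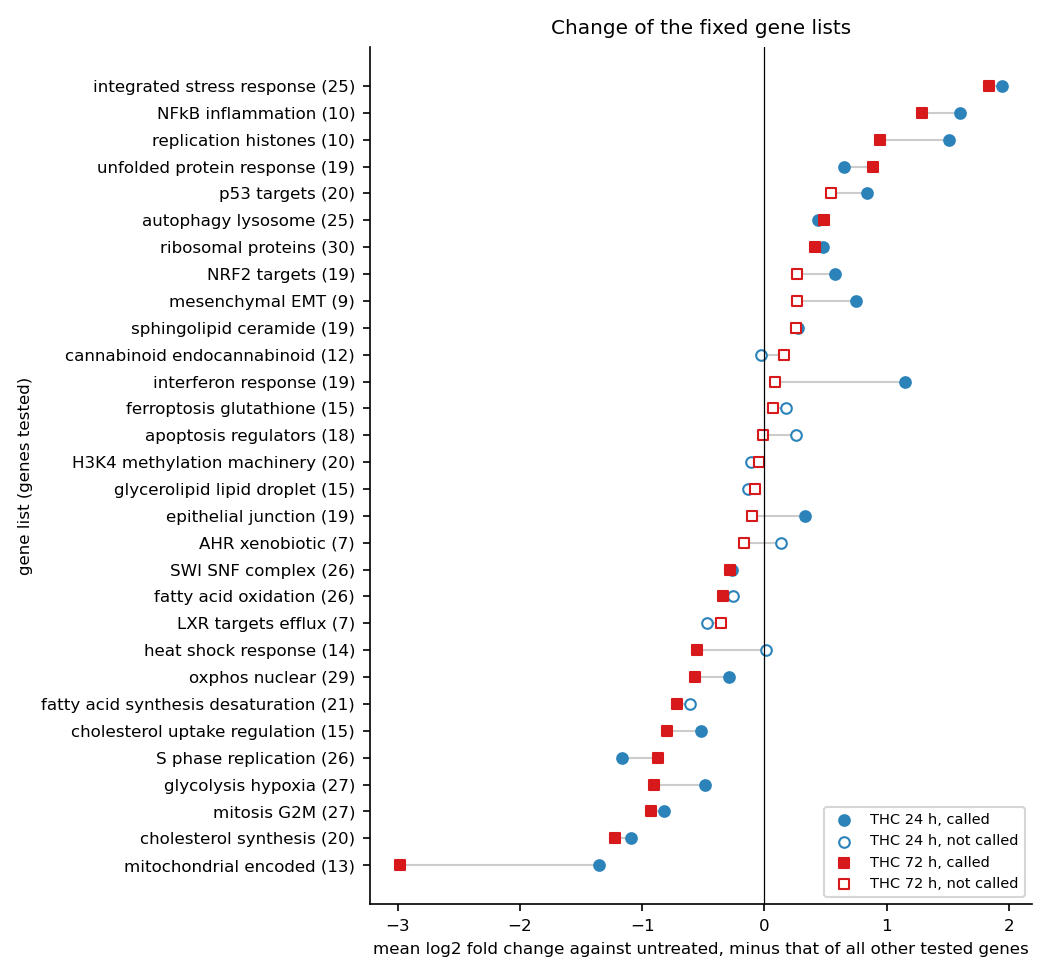
Mean log2 fold change of 30 gene lists minus that of all other tested genes, after 24 h (circles) and 72 h (squares) of THC, filled where limma camera's adjusted p with the preset correlation was under 0.05. In all, 20 lists are filled at 24 h and 17 at 72 h, and with an estimated correlation 2 and 3 would be.

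Of the genes called at 24 h and at 72 h, 2710 were higher at both times and 3819 lower at both, while 1530 were called in opposite directions (1211 after centring). Independent lists of these sizes would share 1376.4, 2348.4 and 3984.8 genes. Unchanged groups simulated against the same untreated libraries shared 0 calls in all 100 draws, which follows from their yielding almost no calls and gives no value for the overlap. Fold changes correlated across genes with r = 0.698, against a mean of 0.502 and at most 0.580 in the simulations, and with a covariance of 0.388 against 0.00822. The simulated groups share their untreated libraries too, so their covariance, at most 0.0102, is what the spread of shared controls adds. This argues against that spread as the source of most of the covariance. A shift common to the 3 untreated libraries is not simulated and stays open, since they cannot be split into groups of at least 2. Genes are not independent replicates.

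The direct comparison of 72 h with 24 h asked which genes moved between the times. With no untreated library labelled for either time, such moves may follow time in culture as well as THC. Interferon-linked genes fell back: ISG15 went from 833 ± 249 to 135 ± 16.3 TPM (-2.58, adjusted p = 8.94e-07), IFIT1 from 98.0 ± 3.12 to 17.3 ± 0.643 (-2.44, adjusted p = 6.82e-10) and the interferon IFNL1 from 18.8 ± 2.53 to 1.08 ± 0.308 (-3.25, adjusted p = 1.33e-07). ARID1A rose from 18.6 ± 1.3 to 33.8 ± 2.04 TPM (0.82, adjusted p = 1.69e-06). PCNA rose from 45.3 ± 1.52 to 140 ± 11.7 TPM (1.60, adjusted p = 3.88e-08), still under the 268 ± 11.5 of untreated cells. SCD (-0.01, adjusted p = 0.904), FASN (0.14, adjusted p = 0.429) and SREBF1 (-0.14, adjusted p = 0.139) were not called, though without 24 h replicate 2 SREBF1 was (-0.21, adjusted p = 0.0221). SREBF2 fell (-0.27, adjusted p = 0.000575).

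Interferon response genes had 4 up and 13 down of 19 (adjusted p = 2.84e-07; adjusted p = 0.178 with an estimated correlation), including RSAD2 (-2.13) and OASL (-2.12). All 13 mitochondrial mRNAs fell (adjusted p = 1.02e-13; adjusted p = 0.178 with an estimated correlation), with MT-ND4 at -1.62 and MT-CYB at -1.54. The S phase list had 20 up and 1 down of 26 (adjusted p = 0.0157; adjusted p = 0.463 with an estimated correlation), with CCNE2 at 1.57 and FEN1 at 1.21. Heat shock genes had 2 up and 7 down of 14 (adjusted p = 0.00104; adjusted p = 0.178 with an estimated correlation), with HSP90AB1 at -0.96 and HSPA8 at -0.89. Glycolysis and hypoxia genes had 7 up and 13 down of 27 (adjusted p = 0.000432; adjusted p = 0.178 with an estimated correlation), with ADM (-1.59), HK2 (-1.18) and the glucose transporter SLC2A1 (-1.16) down. Epithelial junction genes had 1 up and 10 down of 19 (adjusted p = 0.000715; adjusted p = 0.228 with an estimated correlation), with KRT19 (-0.92) and the cadherin CDH1 (-0.77). Nuclear oxidative phosphorylation genes had 10 up and 12 down of 29 (adjusted p = 0.0236; adjusted p = 0.228 with an estimated correlation), with ATP5F1B at -0.46 and NDUFA4 at 0.40.

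A further 5 called lists lost their call after centring. The unfolded protein response had 15 up and 0 down of 19 (adjusted p = 0.0236; adjusted p = 0.46 with an estimated correlation; 0.143 centred), with CRELD2 (1.15), SYVN1 (1.10) and SEL1L (0.91). NRF2 targets had 6 up and 9 down of 19 (adjusted p = 0.0236; adjusted p = 0.251 with an estimated correlation; 0.0755 centred), with TKT at -1.12 and GCLC at 0.84. For p53 targets it was 6 up and 8 down of 20 (adjusted p = 0.0236; adjusted p = 0.228 with an estimated correlation; 0.0899 centred), with GADD45A at -1.43 and the repair gene XPC at 1.09. Mesenchymal genes had 1 up and 3 down of 9 (adjusted p = 0.0236; adjusted p = 0.178 with an estimated correlation; 0.0899 centred), with SNAI2 at -0.87, and VIM at 0.24 but -0.07 centred. Replication histones had 2 up and 5 down of 10 (adjusted p = 0.0236; adjusted p = 0.178 with an estimated correlation; 0.166 centred), H1-2 at -1.3 and H2BC5 at 0.85. No call was made for cholesterol synthesis (8 up and 4 down of 20, adjusted p = 0.747), uptake (6 and 5 of 15, 0.211), fatty acid synthesis (11 and 5 of 21, 0.727), LXR targets (4 and 0 of 7, 0.88), glycerolipid (9 and 2 of 15, 0.859) or fatty acid oxidation genes (13 and 5 of 26, 0.999). The same held for sphingolipids (10 and 3 of 19, adjusted p = 0.999), SWI/SNF (14 and 5 of 26, 0.88), the H3K4 machinery (14 and 4 of 20, 0.589), the integrated stress response (9 and 6 of 25, 0.268), autophagy (14 and 2 of 25, 0.558) and AHR genes (1 and 3 of 7, 0.0718). It also held for endocannabinoid genes (7 and 1 of 12, adjusted p = 0.54), mitosis (14 and 3 of 27, 0.88), apoptosis (8 and 5 of 18, 0.225), ribosomal proteins (18 and 3 of 30, 0.558), NF-κB (4 and 3 of 10, 0.244) and ferroptosis (6 and 6 of 15, 0.354).

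Named single genes that rose from 24 h to 72 h included LINC00205 (2.55 ± 0.334 to 22 ± 0.664 TPM, 2.70), TREM1 (2.41), VASH1 (2.32), CUTALP (2.31), HYAL3 (2.23), FAM200C (2.22) and C22orf46P (2.17). The rises of RNA5S1 (2.60), BCAN-AS1 (2.52) and ZNF407-AS1 (2.28) are uncertain, since near-identical copies or an opposite gene could share their reads and strand use in counting is not stated. Falls included CST6 (-3.59), CCL5 (-3.25), ANGPTL4 (-3.20), PADI1 (-3.05), AMBP (-2.62) and the secreted matrix protein CCN1 (141 ± 1.5 to 22.2 ± 0.939 TPM, -2.61), with CCL3L3 (-2.87) and MKKS (-2.79) uncertain for the same reason. Limma called 7546 genes as higher and 2445 as lower, 1217 and 268 at least 2-fold, and 73.9% of genes had non-overlapping groups, against 10% by chance. The median change was 0.26. Centring (a shift of 0.30) gave 4176 up and 5217 down, the rising share going from 75.5% to 44.5%, with 235 genes called in opposite directions by both. Rescaling without mitochondrial and ferritin genes gave 72.7%. Centred counts up and down were 2 and 14 for the interferon response, 16 and 3 for S phase, 1 and 10 for heat shock, 3 and 20 for glycolysis, 0 and 15 for epithelial genes and 0 and 20 for oxidative phosphorylation. Adjusted over the list alone, glycerolipid genes had 10 up and 2 down, and each of the other 29 lists had the counts given over all genes. Of 12 lists called, 0 were called by camera with an estimated correlation (6 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 25. Median, mean, difference from other genes and test disagreed in sign for 10 lists, none of them called.

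**Figure D3:**
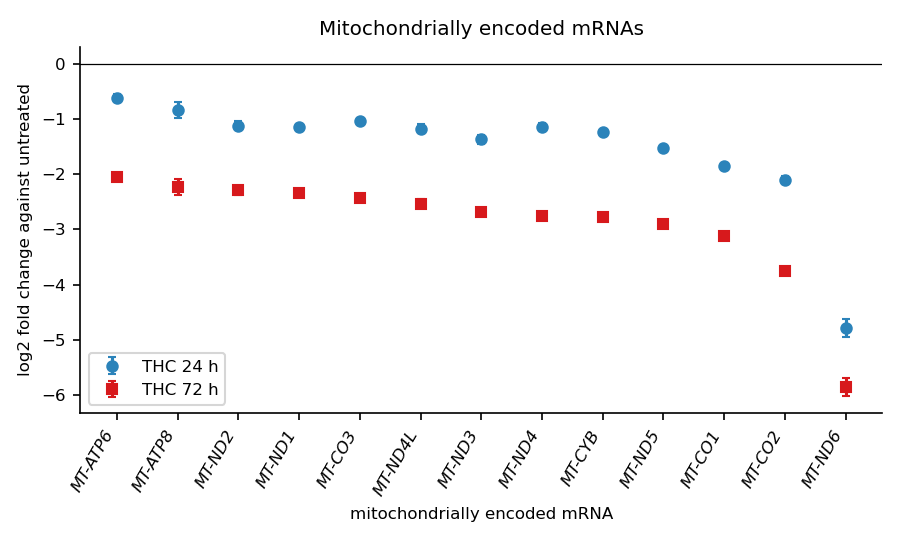
Log2 fold change against untreated cells, with standard errors, of the 13 mitochondrially encoded mRNAs after 24 h and 72 h of THC. All lie below 0, from -0.63 (MT-ATP6) to -4.79 (MT-ND6) at 24 h, with MT-ND6 at -5.86 at 72 h.

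ATAC-seq asked whether THC changed accessible DNA. Near LAMA5, a laminin gene on chromosome 20, a peak at 62366485 to 62366620 was listed in 3 of 3 untreated and 0 of 3 THC libraries at 24 h, and LAMA5 RNA moved by -1.0 (GRCh38 coordinates throughout). Peaks were lost in the same sense at the ends of DPYSL2 on chromosome 8 (26513790 to 26514306, RNA -1.91) and AMIGO2 on chromosome 12 (47078865 to 47079051, RNA -1.40). They were lost as well at KLK6 on chromosome 19 (50968813 to 50968957, RNA 1.28) and COMETT on chromosome 7 (116686777 to 116687089, RNA 1.13), whose RNA rose. At 72 h lost peaks lay at THEMIS2 (chromosome 1, 27872461 to 27872597, RNA 2.38), ISG20 (chromosome 15, 88636159 to 88636323, RNA 2.05), LAMA5 (62367273 to 62367394, RNA -1.81), TSPAN7 (X, 38561097 to 38561783, RNA -1.73) and GPRC5B (chromosome 16, 19886346 to 19886524, RNA -1.56). The 1 gained peak at the marked end of a called gene was at KLHDC7B on chromosome 22 (50545660 to 50546282), whose RNA went from 0.0277 to 12.6 ± 0.946 TPM (3.73) at 72 h.

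At the H3K4me3-marked end of ARID1A an ATAC peak was listed in 3 of 3 libraries of each group, as it was for SREBF2 and FASN and at both ends of SCD, which are both marked. SREBF1 is also marked at both ends. At its upper end, where all 6 H3K4me3 libraries had a peak, an ATAC peak was listed in 3 untreated, 3 24 h and 2 72 h libraries. At its lower end, with the mark in 2 untreated and 2 THC libraries, it was listed in 0 of each group. Peaks covered 37.5 ± 6.39% of the 1 kb on each side of the ARID1A end in untreated libraries, 27.1 ± 9.52% at 24 h (limma adjusted p = 1) and 21.8 ± 5.10% at 72 h (adjusted p = 0.817). Over 8839 such windows the mean share was 35.3% untreated, 31.6% at 24 h and 30.7% at 72 h. Limma called 0 windows at either time, with 177 and 511 at an unadjusted p under 0.05.

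Merged over the 9 libraries there were 239554 ATAC regions. At 24 h, 193 were listed in all THC and no untreated libraries and 1657 the reverse, while 32792 were listed in all 6. At 72 h, 224 were gained, 3038 lost and 22578 listed in all 6. Lost regions had median lengths of 264 bp at 24 h and 196 bp at 72 h and gained ones of 268 and 445.5 bp, against 602 and 745 bp for those in all 6. At 24 h 52.4% of lost regions lay inside genes, 34.6% between genes and 13% at gene ends, where 5.70% of gained regions and 38.9% of the regions in all 6 lay. At 72 h 12.9% of lost and 5.80% of gained regions lay at gene ends, against 45.0% of those in all 6. The longest lost region at 24 h spanned 1522 bp and overlapped WDR70 (chromosome 5, 37414939 to 37416460). At 72 h the longest lost region spanned 1788 bp and overlapped CSPG5 (chromosome 3, 47577614 to 47579401). The longest gained ones were 1538 bp on chromosome 11 (54178193 to 54179730) and 2752 bp on chromosome 1 (121751810 to 121754561). Neither overlapped a gene, and whether reads map uniquely there was not examined. With equal lists of the top 38495 peaks per library, 454 regions were gained and 377 lost at 24 h, and 520 and 941 at 72 h, so the balance at 24 h turned. Over all peaks, leaving out a library, which asks for presence in fewer libraries, raised the counts. At 24 h gained regions numbered 814, 696 and 477 without 24 h replicates 1, 2 and 3 and 397 and 514 without untreated replicates 1 and 3. Lost ones numbered 2661, 10115 and 3567 without untreated replicates 1, 2 and 3 and 4190 without 24 h replicate 3. At 72 h gained regions numbered 452, 857 and 860 without 72 h replicates 1, 2 and 3 and 404 and 365 without untreated replicates 1 and 3. Lost ones numbered 12685 and 5221 without untreated replicates 2 and 3 and 10622 without 72 h replicate 3.

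Untreated libraries held 105279 ± 43172 peaks, 24 h libraries 65903 ± 10982 (a change of -37.4%, exact permutation p = 0.2, 2-sided) and 72 h libraries 56762 ± 21717 (-46.1%, exact permutation p = 0.2), where 3 against 3 cannot go below 0.1. Peaks covered 27.0 ± 8.90, 19.7 ± 5.29 and 20.7 ± 6.32 Mb (exact permutation p = 0.3 and 0.4). Untreated replicate 1 held 150884 peaks, and without it the differences were -16573.7 at 24 h and -25715.3 at 72 h, while without untreated replicate 2 they were -59494.7 and -68636.3. Pairs of libraries of one group shared 41.4% of the regions listed in either on average, and pairs from different groups 39.5%. With equal lists the shares were 62.2% and 59.4%, and these differences were not tested.

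**Figure D4:**
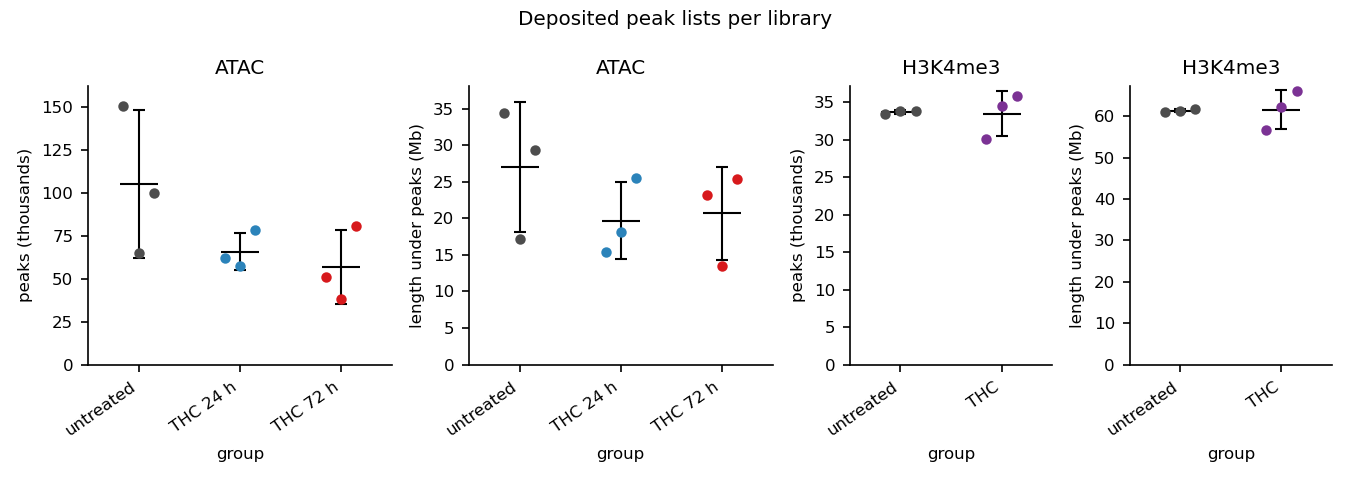
Number of peaks (axis in multiples of 1000) and length under peaks in Mb for each ATAC and H3K4me3 library, with a dot per library, a line at the mean and bars of 1 SD (n = 3). ATAC peak lists run from 38495 to 150884 peaks, and untreated libraries average 105279 ± 43172.

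H3K4me3 asked whether the promoter mark moved with THC. Regions at gene ends gained the mark in 3 of 3 THC and 0 of 3 untreated libraries at KCNG1, a potassium channel gene (chromosome 20, 51022284 to 51023530, 72 h RNA 1.62), GARS1-DT (chromosome 7, 30548570 to 30549366, 72 h RNA 1.22) and BMP8B (chromosome 1, 39788649 to 39789611, 24 h RNA -0.91). RNA is given at a single time per gene, under a rule that ranks by the size of the RNA change, and the other time is left out. The longest gained region, 1751 bp, overlapped ARID1B, which encodes an alternative to ARID1A in SWI/SNF (chromosome 6, 157017633 to 157019383). The longest lost one, 2296 bp, overlapped LOC128966623 and RUFY1 (chromosome 5, 179609824 to 179612119). Both were named for their length and not for lying at a gene end, and no RNA change was set beside them. ARID1A, SREBF1, SREBF2, FASN and SCD carried the mark in 3 of 3 libraries of both groups, and the 2 kb on each side of the ARID1A end were 100% covered in both. CNR1 carried no H3K4me3 peak at an end. GPR55 had one at its lower end in 2 of 3 untreated and 3 of 3 THC libraries, and at its upper end in 0 of each group. Without the strand it is not known whether that lower end is the promoter.

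Of 47473 H3K4me3 regions, 305 were gained, 184 lost and 22662 listed in all 6 libraries. Leaving out THC replicates 1, 2 and 3 in turn gave 943, 523 and 479 gained and 248, 391 and 494 lost, and leaving out untreated replicates 1, 2 and 3 gave 424, 520 and 494 gained and 508, 472 and 446 lost. The balance therefore turned without THC replicate 3 and without untreated replicate 1. Gained and lost regions had median lengths of 791 and 864 bp, against 2542 bp for those in all 6. The lists held 33735 ± 230 untreated and 33517 ± 3032 THC peaks (exact permutation p = 1, 2-sided) over 61.3 ± 0.385 and 61.6 ± 4.72 Mb (p = 0.9, exact permutation). Of 9045 gene-end windows, limma called 3: PHF2 (90.2% to 100%, adjusted p = 0.000419), SEPHS1 (90.5% to 100%, adjusted p = 0.00145) and SEPSECS (100% to 95.3%, adjusted p = 0.012). These genes lie outside the fixed naming rule and were chosen after their values were seen. All are at the ceiling of the share in one group, and 0 were called with 5 kb windows or after centring. Leaving out 1 library gave 3 to 12, with 12 and 8 without THC replicates 3 and 2 and 7 and 5 without untreated replicates 2 and 1.

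**Figure D5:**
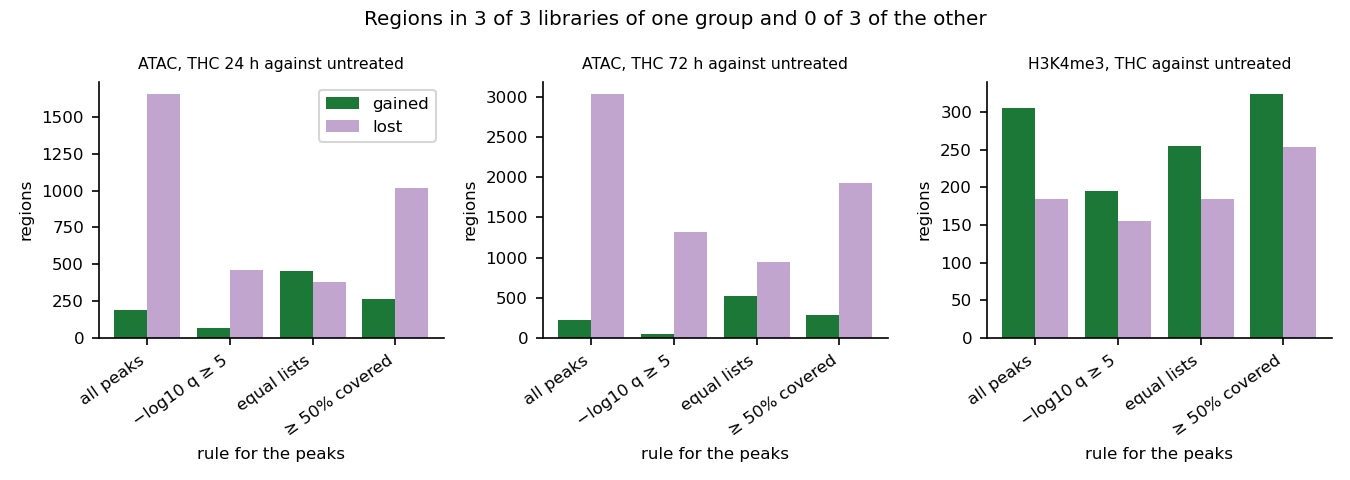
Regions gained (in every THC and no untreated library) and lost (the reverse) in ATAC at 24 h and 72 h and in H3K4me3, counted over all peaks, peaks with -log10 q of at least 5, equal lists and peaks covering at least 50% of a region. With all peaks ATAC gained 193 and lost 1657 at 24 h, and with equal lists gained 454 and lost 377.

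The assays were joined at gene ends to ask whether promoter peaks and RNA moved together. The 27 tested genes with a lost ATAC region at their marked end at 24 h included 10 whose RNA rose and 14 that fell (camera adjusted p = 0.381; adjusted p = 0.561 with an estimated correlation). At 72 h 18 of 64 rose and 27 fell (adjusted p = 0.371; adjusted p = 0.561 with an estimated correlation). Genes that gained H3K4me3 numbered 7, of which 2 rose and 2 fell at 24 h (adjusted p = 0.371) and 5 rose and 1 fell at 72 h (adjusted p = 0.304). Fisher's exact tests of the shares that rose or fell gave adjusted p-values from 0.4 to 1. Across genes, Spearman correlations of the change in covered share with the RNA change lay between 0.014 and 0.044, and genes are not independent replicates.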

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

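The tests of patterns and of other groupings of the libraries given here were chosen after the results were seen, except the comparison of lncRNA genes with protein-coding genes of like level, the test for genomic DNA and the regroupings for RNA at gene ends with lost or gained regions. The values that follow were picked out because RNA in THC libraries differed between 24 h and 72 h by limma's direct comparison of the times. Both times share the same untreated libraries, whose labels give no time. A change with time in culture therefore cannot be told apart from one with longer THC exposure. Groups of 3 libraries were not tested for outlying samples.

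For gene lists, the mean log2 change from 24 h to 72 h minus that of other genes was -1.63 for mitochondrially encoded mRNAs, -1.07 for the interferon response, -0.568 for heat shock, -0.561 for replication histones, -0.480 for mesenchymal genes and -0.433 for epithelial junction genes. It was -0.416 for glycolysis and hypoxia, -0.310 for NRF2 targets, -0.297 for p53 targets, -0.280 for nuclear oxidative phosphorylation, 0.231 for the unfolded protein response and 0.295 for S phase. With an estimated correlation 0 of these 12 lists were called (lowest camera adjusted p = 0.178), and after centring the unfolded protein response, NRF2, p53, mesenchymal and histone lists were not called. For genes that moved in opposite directions at the times, the log2 change from 24 h to 72 h was 2.70 for LINC00205, 2.52 for BCAN-AS1, 2.32 for VASH1, 2.31 for CUTALP, 2.28 for ZNF407-AS1, 2.23 for HYAL3, 2.22 for FAM200C and 2.17 for C22orf46P. It was 1.15 for CRELD2, 1.09 for XPC, 0.91 for SEL1L and 0.84 for GCLC. Downward it was -3.20 for ANGPTL4, -2.44 for IFIT1, -1.83 for H2AC20, -1.18 for HK2, -0.96 for HSP90AB1, -0.89 for HSPA8, -0.77 for CDH1 and -0.53 for ESRP2. In all, 1530 genes were called in opposite directions at the 2 times, 1321 of them lower at 24 h and higher at 72 h and 209 the reverse. That imbalance runs with the shift of the library medians (-0.22 at 24 h and 0.09 at 72 h): after centring 548 were lower and then higher and 663 the reverse, and 757 genes were called in opposite directions in both fits.

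Pattern 1 is the fall of the 13 mitochondrially encoded mRNAs, whose median at 72 h lay at -2.75 relative to that of all tested genes. A shift of TPM scale would move both medians alike, so this value argues against it as the whole cause. The ribosomal protein mRNAs, whose median lay 0.413 above that of all genes, did not fall as a lower share of cytoplasmic RNA would have them do. They are a single class of mRNA, however. ACTB and TUBA1B mRNA, chosen after their values were seen, fell at 72 h while the nuclear RNA NEAT1 rose, so a lower share of cytoplasmic RNA stays open. Reads moved to nuclear copies are argued against by the summed TPM of those copies, which changed by -662 from untreated cells to 72 h. Loss of a share of mitochondria that lowers each mRNA alike is argued against as the whole cause at 24 h by the range of 4.16 between the 13 log2 changes (1.48 without MT-ND6, which fell by 4.79), but stays open from 24 h to 72 h, where the range was 0.586 with a largest standard error of 0.164. An effect of THC on these mRNAs stays open, and neither how it would lower them unequally nor the RNA extraction was tested.

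Pattern 2 is the rise of lncRNA genes from 24 h to 72 h, of which 542 of 827 (65.5%) rose and 81 fell, with a median of 0.55, against 54.9% rising of all tested genes, 54.4% of protein-coding genes and 66.1% of 248 transcribed pseudogenes, after 160 lncRNA genes had risen and 434 fallen at 24 h. That median lay 0.296 above that of all genes, which argues against a scale shift, and above all 10000 protein-coding lists matched on mean TPM, whose median was 0.393 and highest value 0.472, which argues against low level as the whole cause. Genomic DNA in the 72 h libraries stays open: the summed TPM of protein-coding genes without an H3K4me3 peak was 1.20 times as high at 72 h as at 24 h (4414 ± 144 against 3686 ± 30.4, n = 3), which lies between the values set for and against. A response of these genes to the longer exposure or to time in culture may also be the cause, and neither was tested.

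Pattern 3 is the excess of lost over gained ATAC regions, 8.59 to 1 at 24 h and 13.6 to 1 at 72 h. With lists of equal length the ratio at 24 h was 0.830, so the length of the lists could account for the excess there. At 72 h it was 1.81, but another grouping of the 6 libraries, also with lists of equal length, reached 3.55. For this ratio THC therefore cannot be told apart from other differences between the samples. The number of gained and lost regions together is a separate matter: with equal lists it was 831 at 24 h and 1461 at 72 h, above the highest other groupings (599 and 1043).

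For all regroupings, the 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. For changed genes 1 of 10 splits gave as many as the real one at 24 h (10442, highest other 2), at 72 h (10153, highest other 1) and between the times (9724, highest other 1). Every other split mixes the groups, so a difference between them widens its spread and lowers its count of genes. Those low counts are therefore no measure of chance. For called lists 1 of 10 did so, with 20 and a highest other of 13 at 24 h, 17 and 16 at 72 h and 12 and 9 between the times. Mixed splits thus still called lists, so a number of called lists does not by itself point to THC. For gained and lost regions together, 2 of 10 splits reached the real number in ATAC at 24 h (1850, highest other 4109) and at 72 h (3262, highest other 5234), and 1 of 10 in H3K4me3 (489, highest other 352). The larger ATAC splits set untreated replicate 2 with THC replicates 1 and 2 against the rest. With equal lists these same splits gave 599 and 1043 regions, below the real 831 and 1461, and in H3K4me3 the real split gave 439 and the highest other 225. For gene-end windows in ATAC the real count was 0 at both times, which all 10 splits reach by construction, so this count says nothing of chance (highest other 730 at 24 h and 2 at 72 h). For H3K4me3 windows 5 of 10 splits reached the real 3 (highest other 7). The split with 730 windows set the 3 longest lists, untreated replicates 1 and 3 and 24 h replicate 3, against the 3 shortest. With equal lists it gave 295, so it points to a structure of the samples that goes with list length and that equal lists did not remove. For the RNA of genes with lost ATAC regions, 5 of 10 splits gave a camera p as small at 24 h (real 0.373, lowest other 0.103) and 7 at 72 h (real 0.278, lowest other 0.06). For genes with gained H3K4me3 regions 5 of 10 did at 24 h (real 0.25, lowest other 0.00732) and 3 at 72 h (real 0.081, lowest other 0.0152).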

How the results depend on the processing

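The rescaling of TPM without mitochondrial and ferritin genes was chosen after seeing the data, and all other alternatives before. Of 3450 log2 fold changes of named genes under alternatives 3440 kept their direction and side of the threshold, as did 883 of 990 list values (22 reversed, 29 became and 56 ceased to be called). Counts stayed within 1.5 times in 42 of 45 cases for changed genes, 27 of 33 for called lists, 3 of 4 for shared calls and 16 of 60 for regions, and 23 of 30 promoter results, 20 of 21 peak numbers, 20 of 21 covered lengths and 10 of 12 RNA changes at gene ends were the same. Replicate numbers do not pair the RNA libraries (correlations of deviations from -0.199 to 0.252 for the same number and -0.235 to 0.219 for others). In ATAC gene-end windows 6 of 9 same-number pairs, those of replicates 2 and 3, correlated over 0.1, and 2 of 18 others did (-0.120 to 0.322 and -0.338 to 0.245). Replicate 1 did not, so shared numbers are there at most a hint from the data. Replicate 2 also had the shortest list of each group (65042, 57356 and 38495 peaks), so pairing and list length cannot be told apart. The block called 0 ATAC windows, as the fit without it did. In H3K4me3 0 of 3 same-number pairs did (-0.00905 to 0.0151, others -0.0228 to 0.0168). The replicate number as a block gave 10577, 10077 and 10032 changed genes, and moved the H3K4me3 windows to 0. With it camera's direction turned for fatty acid oxidation between the times, while the mean minus that of other genes stayed at -0.0876 (camera adjusted p = 0.999 without the block and 0.961 with it). Depth is unknown, so no limit from it can be given.

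The cause was not tested for the changes that follow, except that stricter rules leave fewer genes or regions and left-out libraries leave fewer samples. With a fold threshold of 2, 2190, 1887 and 1485 genes were called at 24 h, at 72 h and between the times, and 906 shared. Median centring put, between the times, VIM at -0.0670 and FASN at -0.16. It left 7 lists called between the times and turned camera's direction for 4 that were not called. Their means minus those of other genes, which centring leaves as they are, were -0.0193 for sphingolipids, -0.0182 for SWI/SNF, -0.101 for mitosis and -0.0674 for ribosomal proteins. A pseudocount of 0.1 also turned camera's direction for fatty acid oxidation between the times, at a difference of -0.104. An estimated correlation left 2, 3 and 0 lists called, and fry called 27 at 72 h and 25 between the times. Lists for which fry's direction was the opposite had means of -0.0487 (AHR, 24 h), 0.0338 (H3K4 machinery, 72 h) and -0.0234 (epithelial, 72 h). Between the times such means were 0.133 for cholesterol synthesis, -0.0219 for uptake, 0.160 for fatty acid synthesis, 0.172 for oxidation, 0.157 for the integrated stress response and 0.153 for ferroptosis.

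Peaks with -log10 q of at least 5 gave 66 gained and 460 lost ATAC regions at 24 h, 55 and 1324 at 72 h, and 195 gained H3K4me3 regions. Equal lists gave 454 and 377 at 24 h and 520 and 941 at 72 h. A cover of at least 50% gave 1015 and 1930 lost. Presence in at least 2 of 3 libraries gave 1601 and 13029, 1721 and 16156, and for H3K4me3 1335 and 1058. H3K4me3 windows of 5 kb and centred shares gave 0 calls each. With equal lists the RNA of genes with lost ATAC regions at 24 h differed from other genes by -0.0548, and the 24 h RNA of genes with gained H3K4me3 regions by -0.253.

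Leaving out each library in turn gave ranges from -0.0276 to 0.00538 (apoptosis, 72 h), 0.0724 to 0.103 (interferon, 72 h), -0.0823 to 0.275 (FASN between the times), -0.0585 to 0.0472 (SCD), -0.0995 to -0.0685 (fatty acid oxidation), -0.0335 to -0.00726 (sphingolipids) and -0.127 to -0.0826 (mitosis). Differences in H3K4me3 peaks ranged from -1399.5 to 1491 and in covered length from -1.92 to 2.78 Mb. ATAC regions ranged from 266 to 814 gained and 2111 to 10115 lost at 24 h and 311 to 860 and 3269 to 12685 at 72 h. H3K4me3 gave 424 to 943 and 248 to 508, and its windows 3 to 12. Called lists ranged from 19 to 20 at 24 h and 17 to 18 at 72 h, where sphingolipids were called without 72 h replicate 1.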

Other observations

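The genes and groups here were chosen after their values were seen, and the tests on distance to genes likewise. MT1X and MT2A, which encode metal-binding metallothioneins, rose, MT1X from 49.4 ± 5.88 to 192 ± 3.30 TPM at 24 h and 320 ± 63.8 at 72 h (log2 fold changes 1.95 and 2.66), and MT2A from 467 ± 34.9 to 2193 ± 464 and 1646 ± 363 (2.21 and 1.79). The noncoding RNA GAS5, a host of small nucleolar RNAs, rose from 168 ± 8.27 to 1289 ± 62.3 and 1068 ± 86.8 TPM (2.93 and 2.66, limma adjusted p = 2.64e-10 and 4e-10), and the nuclear RNA NEAT1 from 325 ± 7.46 to 1043 ± 26.2 and 845 ± 10.5 TPM (1.68 and 1.37). The actin mRNA ACTB was 6108 ± 181 TPM untreated, 6116 ± 854 at 24 h (-0.01, limma adjusted p = 0.947) and 1950 ± 138 at 72 h (-1.65, limma adjusted p = 9.7e-08), while the tubulin mRNA TUBA1B was at -0.94 and -1.73. CCN2, a secreted matrix protein gene, was at -1.82 and -2.56, while ANKRD1 rose by 2.33 at 24 h and stood at -0.06 at 72 h (limma adjusted p = 0.547). Near-identical copies make single actin, tubulin and metallothionein genes uncertain.

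The listed levels of the mitochondrial ribosomal RNAs rose at 24 h, where the mitochondrial mRNAs fell. Whether the total RNA kit removed ribosomal RNA was not examined, so how far these values follow the level in cells is open. MT-RNR1 went from 613 ± 39.5 TPM to 2024 ± 37.2 at 24 h (1.72, limma adjusted p = 1.93e-09) and 1016 ± 45.6 at 72 h (0.73, limma adjusted p = 7.2e-07). MT-RNR2 rose by 0.68 at 24 h and was at -0.62 at 72 h. From 24 h to 72 h both fell, MT-RNR1 at -0.99 and MT-RNR2 at -1.3, as the mRNAs did. Of 30 tested small nucleolar RNAs 8 rose and 1 fell at 24 h, 2 rose and 4 fell at 72 h, and 0 rose and 10 fell from 24 h to 72 h.

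ATAC regions gained at 72 h lay far from genes more often than other regions. Of 224 such regions 124 (55.4%) were over 0.5 Mb from any protein-coding or lncRNA gene, against 53 of 22578 (0.235%) listed in all 6 libraries, 4 of 3038 lost at 72 h and 8 of 193 gained at 24 h. With equal lists it was 85 of 520 (16.3%). They gathered on chromosome 5 (32 regions between 47450697 and 49577118), 19 (30 between 24925135 and 27180532), 1 (22 between 122539295 and 124775041) and 11 (19 between 51274666 and 53931854). Peaks that far from genes numbered 424 ± 115 per untreated library, 582 ± 117 at 24 h (exact permutation p = 0.2, 2-sided) and 1393 ± 573 at 72 h (exact permutation p = 0.1, the smallest 3 against 3 can give), with 733, 1695 and 1752 in the 72 h libraries. With equal lists the exact permutation p-values were 0.2 and 0.1. There 72 h replicates 1, 2 and 3 held 1192, 1695 and 302 such peaks, and 24 h replicate 2 also held 302. The high numbers thus came from 72 h replicates 1 and 2. Their full lists held fewer peaks with -log10 q of at least 5 (16506 and 8148) than that of replicate 3 (29052). H3K4me3 lists held 3 to 5 such peaks per library. Whether reads map uniquely in these spans was not examined, so these peaks are not shown to mark DNA that opened. No explanation was tested.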
